A study of Methylotuvimicrobium alcaliphilum 20Z with 8 samples.

How the data were processed

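RNA was sequenced from 8 libraries of Methylotuvimicrobium alcaliphilum 20Z, a bacterium of saline and alkaline habitats that grows on methane. The labels place 4 libraries in batch culture under 20% CH4, 5% O2 and 75% N2. They place 2 libraries in a bioreactor under 20% CH4, 20% O2 and 60% N2, and 2 in a bioreactor under 20% CH4, 5% O2 and 75% N2. The labels call the libraries of a group biological replicates. Batch cultures of 50 ml grew in vials of 250 ml that were flushed for 15 min and shaken at 200 rpm, and cells were taken in mid-exponential growth. The bioreactor libraries carry the same growth text as the batch libraries, so feed, density and stage in the bioreactor are not given in the sources used here. Another label calls the 5% O2 bioreactor libraries no_o2. The stated gas mix was used, and the libraries are named 5% O2 throughout. Date-like tokens in the library names differ between the gas groups, with 0 of them shared, so gas mix and whatever those tokens mark are confounded. Another token, br3, is shared by replicate 2 at 20% O2 and both replicates at 5% O2, while replicate 1 at 20% O2 carries br1. The meaning of these tokens is not given in the sources used here. In the names of the batch libraries, br is followed by the replicate number. Where br3 marks a vessel, the 5% O2 libraries came from 1 vessel, and the spread between them may be technical. The p-values rest on a spread shared by all 8 libraries, which would then hold no spread between vessels at 5% O2.

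Reads of 36 bp were processed by the authors with BWA 0.6.1 and SAMtools 0.1.17, per the submitters' processing notes, which do not say which step each tool served. The counting tool, genome build, use of strand and treatment of reads shared between genes are not given in the sources used here. The deposited values were treated as a score, namely RPKM (reads per kilobase of gene, scaled to the assigned reads of the library) that the authors had rounded to whole numbers. Multiplied by gene length in kilobases and summed over the genes with a known length, the deposited values came to between 987674 and 990594 per library. With gene lengths permuted among genes 200 times per library, the lowest sum was 1027415. Whole-number rounding coarsens the values of low genes. Read numbers could not be recovered from the steps between low values, so read depth is unknown, and no counting interval or detection floor is given. A count model was not used, because the values are not raw counts, and the test was the one planned for RPKM.

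The table listed 4007 genes by locus tag. Names came from a RefSeq gene table of assembly ASM96853v1, which was used for names and gene lengths only. It matched 3780 tags, left 227 unmatched, and gave a gene symbol for 959 genes. There were 63 symbols carried by more than 1 gene, and the locus tag of the copy is given for those. Of the matched tags, 21 were pseudogenes and 0 were rRNA or tRNA genes. Genes without a symbol in that table could enter no gene list. The symbols mxaF, xoxF, pfp and eda were not among the names, so no result is given under those names, although genes without a symbol were fitted, and pmoA, pmoB and pmoC were present as amoA, amoB and amoC.

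Expression was compared on log2(RPKM + 1). A log2 fold change on this scale understates the change of low genes. The 4001 genes with a mean RPKM of at least 5 over the 8 libraries were fitted in limma 3.58.1 (R 4.3.3) with 3 groups, a spread shared by all 8 libraries, an intensity trend and moderated variances, which gave 10.4 total degrees of freedom. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Comparisons were 20% against 5% O2 in the bioreactor, each bioreactor group against batch, and the mean of both bioreactor groups, weighted equally, against batch. No scaling was added to the deposited RPKM. Values are given as mean ± SD, with n = 4 for batch and n = 2 for each bioreactor group, and log2 fold changes with their standard error (SE) where given.

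Gene lists, the rule for named genes, the tests and most alternatives were fixed before the data were examined. Of 33 lists fixed, 31 matched at least 1 gene, and the list of methanol dehydrogenase and PQQ matched pqq genes only. The lists for hemerythrin and globin genes and for structural RNA matched none and have no result. A list was tested with limma's camera, preset inter-gene correlation 0.01, where at least 5 members were tested. That held for 19 lists, and shorter lists are described by counts. No list call held at adjusted p under 0.05 when camera estimated the correlation from the data. Named genes were the 12 largest rises and 12 largest falls in each comparison among genes with a symbol, adjusted p under 0.05, groups whose values did not overlap, and mean RPKM of at least 20. To these were added up to 4 members of each list with the smallest p, the 15 genes with the highest mean RPKM in batch, amoA, amoB, amoC and edd. Names given outside this rule are stated as such.

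The fits were tested on simulated data with known changes in the real genes. At a log2 change of 1, the fit recovered 57.6% of changed genes for 20% against 5% O2, 68.2% for the 5% O2 bioreactor against batch, 68.2% for the 20% O2 bioreactor against batch and 86.4% for the mean of both against batch. At a log2 change of 0.5 the shares were 7.4%, 14.7%, 17.6% and 29.4% in that order. Over all sizes of change, 6.1%, 4.1%, 4% and 6% of the calls were false. Each simulation changed 68, 66 and 66 of 4001 genes by 0.5, 1 and 2, whereas 42.1% to 56.9% of genes were called in the real comparisons. The adjusted p depends on that share, so the recovered shares may differ from those in the real data. Camera called 0 of 19 unchanged simulated lists and called the list that had been shifted. The simulated genes varied independently of each other, whereas the estimated correlation was 0.232 among the real ribosomal protein genes. The simulation therefore cannot tell how often camera calls unchanged lists whose genes vary together. Alternatives were pseudocounts of 0.1 and 10, other filters, median-ratio and quantile scaling, fits of only the compared groups, no intensity trend, the replicate number as a block, each library left out in turn, an estimated correlation, limma's fry, and the list tests without ribosomal protein genes. Levels, percentiles and plots used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. For batch growth, the median RPKM of each list was set in each library against 10000 random lists of the same size.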

Results

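Transcript levels were measured by RNA sequencing in 8 libraries of the methanotroph M. alcaliphilum 20Z, from batch culture (n = 4), a bioreactor at 20% O2 (n = 2) and a bioreactor at 5% O2 (n = 2). Summed RPKM ranged from 1227159 to 1317971 per library, and the 20 highest genes held 23.4% to 28.12% of it. Across genes, which are not independent replicates, Pearson correlations of log2(RPKM + 1) within groups were 0.968 to 0.990 in batch, 0.984 at 20% O2 and 0.949 at 5% O2. The first principal component placed the 20% O2 libraries at 43.61 and 43.79, batch between -10.6 and -9.42, and the 5% O2 libraries at -28.53 and -19.58.

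**Figure D1:**
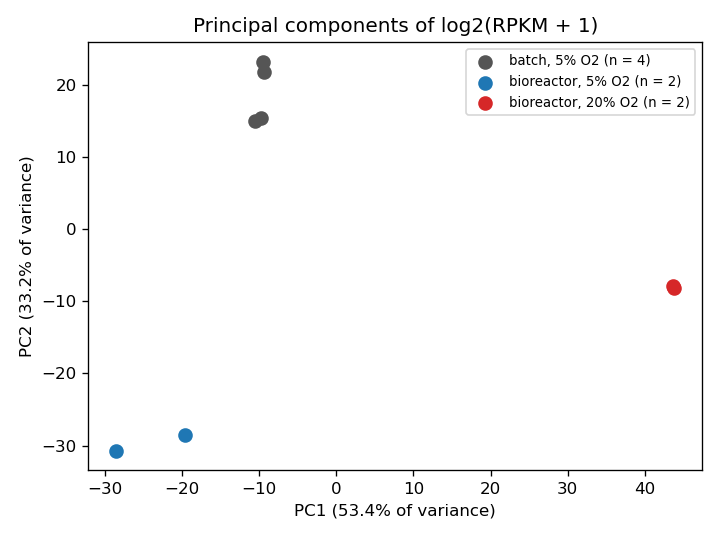
Principal components of log2(RPKM + 1) for the 8 libraries, with PC1 (53.4% of variance) on the horizontal axis and PC2 (33.2%) on the vertical axis; each point is a library, coloured by group. PC1 sets the 2 libraries at 20% O2 apart, and PC2 sets batch, between 14.92 and 23.15, apart from the bioreactor libraries.

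Batch growth was profiled in 4 libraries, which bears on the routes of carbon that are expressed on methane. The genes for particulate methane monooxygenase, which oxidizes methane to methanol, led the transcript pool. Mean RPKM was 74034 ± 2573 for amoC, 50272 ± 1345 for amoA and 49314 ± 1369 for amoB (SD, n = 4), together 13.8% ± 0.37 of summed RPKM. The next named genes were moxG, for a cytochrome that takes electrons from methanol dehydrogenase, at 11513 ± 987, and moxJ, a gene of the same oxidation system, at 7673 ± 545. The genes hxlA and hxlB, for the enzymes that fix formaldehyde into sugar phosphate in the ribulose monophosphate (RuMP) pathway, reached 7362 ± 139 and 5213 ± 231. The other 8 of the 15 highest genes had no symbol, among them MEALZv4_3445 at 18733 ± 1613.

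By list, the RuMP entry genes had a median of 6288 ± 164 RPKM, above 99.6% to 99.7% of random lists in each library. Genes of EMP glycolysis, which splits hexose phosphate, had a median of 734.2 ± 73.7 (9 genes), and those of the Entner-Doudoroff and oxidative pentose phosphate routes 232.2 ± 18.2 (5 genes). The log2 ratio of these medians was 1.66 ± 0.14 (SD, n = 4), a 3.16-fold difference, with values from 1.54 to 1.84. The exact two-sided sign-flip permutation p was 0.13, the smallest that 4 libraries allow. The EMP list held pgi, fba, fbaA, tpiA, gap, gpmI, eno, pyk and ppdK but not pfp. The other list held edd, pgl, gnd and copies of zwf but not eda. The steps of gap, gpmI, eno and pyk also serve the Entner-Doudoroff route, so the ratio does not set one whole route against the other. Against glyA, the only gene of the serine cycle list matched by symbol, the RuMP entry median stood 4.64 ± 0.35 higher on the log2 scale (exact sign-flip p = 0.13, n = 4). Other genes of that cycle may be among the genes without a symbol, so this ratio does not compare the routes. Medians were 1591 ± 141 for ribosomal proteins, 1154 ± 79.8 for ATP synthase, 1090.2 ± 32.5 for pentose phosphate rearrangement, 242.8 ± 14.3 for formaldehyde and formate oxidation, 232.5 ± 40.6 for the list of methanol dehydrogenase and PQQ and 222.2 ± 25 for the TCA cycle. The members of the methanol dehydrogenase and PQQ list were 5 pqq genes, which serve synthesis of the cofactor PQQ, and no gene of the dehydrogenase itself. The fermentation list, at 53.5 ± 2.5, and nitrogen assimilation genes, at 49.5 ± 4, lay above 8.2% to 10.8% and 0.7% to 1.7% of random lists. The fermentation list held 2 genes, pta and acs, of which acs is for acetyl-CoA synthetase, an enzyme that uses acetate. No other gene of that list was matched by symbol, so its level does not stand for fermentation as a whole.

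Bioreactor cultures at 20% and 5% O2 were compared to ask how the gas mix goes with expression within a culture type. All 50 ribosomal protein genes, 22 of 31 amino acid synthesis genes, the nitrogen genes glnK and glnA and the chaperonin genes groES and groL were higher at 20% O2. The flagellar genes fliD, fliS, flgK, flgL, flgM and flgJ, acnA for aconitase and fumC for fumarase were lower. The largest rise among named genes was that of glnK, for a PII protein that signals nitrogen status, from 79.5 ± 43.1 to 1843 ± 98.3 RPKM (SD, n = 2 each; log2 fold change 4.63, SE 0.59, adjusted p = 0.00011). The chaperonin genes groES and groL, whose product folds proteins, rose by 4.49 and 4.28, with groL at 182.5 ± 33.2 and 3540 ± 13.4 RPKM. At the other end, fliD, for the cap of the flagellar filament, fell by 3.81 on the log2 scale, from 10262 ± 694 to 728 ± 4.2 RPKM (adjusted p = 2.1e-07).

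Of 4001 genes tested with limma, 2277 (56.9%) changed, 750 higher and 1527 lower at 20% O2, and 424 and 801 of these by at least 2-fold. The median of all genes was -0.305, which shifted to -0.03 with median-ratio scaling and -0.01 with quantile scaling. The calls then split 1046 higher to 1051 lower and 1046 to 1076, that is, 49.9% and 49.3% higher in place of 32.9%. Relative to the all-gene median, the rises below are therefore larger by that amount and the falls smaller. Among bioreactor libraries, the token br3 in the library names marks replicate 2 at 20% O2 and both replicates at 5% O2. Without replicate 1 at 20% O2, so that all bioreactor libraries in the fit carry that token, limma called 1681 genes, 573 higher and 1108 lower, and camera called 11 lists. That fit has 1 library at 20% O2, which is assumed to vary like the batch and 5% O2 libraries, so it holds no replicate check of that group.

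Further rises were those of rplJ (4.18), rplL (3.95), rplA (3.00) and rplK (2.81), which encode proteins of the large ribosomal subunit. The ferrous iron transporter gene feoB (MEALZv4_2489) rose by 3.45, from 32 to 360 RPKM, and nirB, for the large subunit of nitrite reductase, by 3.29. The cobalamin synthesis gene cobM rose by 3.06, htpG, for the Hsp90 chaperone, by 2.92, and atpG, for the gamma subunit of ATP synthase, by 2.78. The 5% O2 libraries differed in atpG, at 126 and 437 RPKM, and its rise was 1.88 without replicate 1 and 3.67 without replicate 2 at 5% O2. Further falls were those of fliS (-3.68), for the flagellin chaperone, flgM (-3.37), for the anti-sigma factor of flagellar genes, flgK (-3.03) and flgL (-2.80), for the hook-filament junction, and flgJ (-2.63), for assembly of the flagellar rod. Values for smbP, a small metal-binding protein, went from 5851 ± 276 to 748.5 ± 3.5 RPKM (-2.96). Lower at 20% O2 were also acnA, for aconitase (-2.78), one copy of shc (MEALZv4_2523, -2.76), for squalene-hopene cyclase, vgrG, for the spike of the type VI secretion system (-2.73), treZ, a trehalose synthesis gene (-2.62), and fumC, for fumarase (-2.39). All of these had adjusted p of 0.00038 or below.

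**Figure D2:**
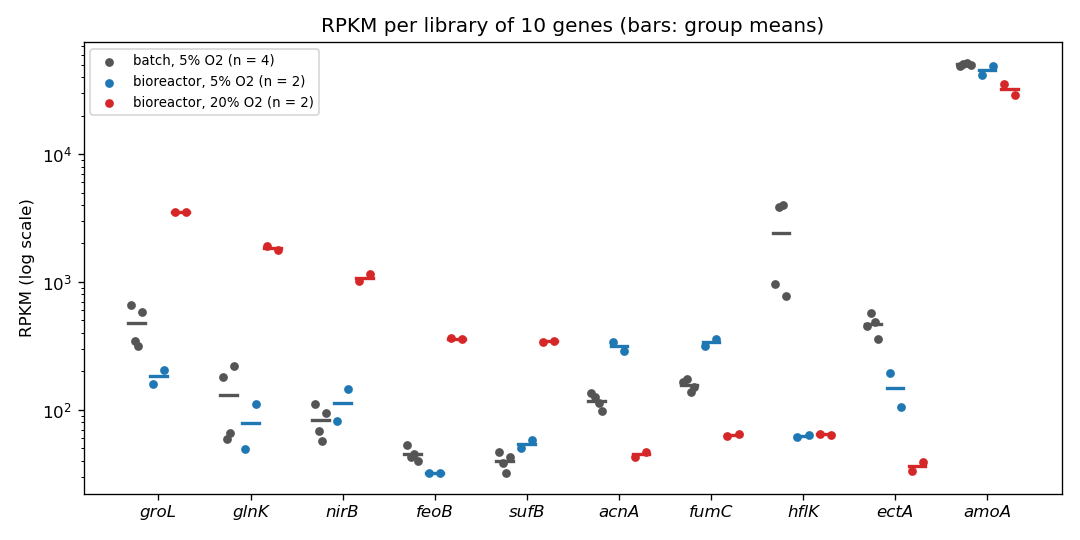
RPKM on a logarithmic axis for 10 genes (feoB is MEALZv4_2489 and hflK is MEALZv4_4003); points are libraries, coloured by group, and bars are group means. The chaperonin gene groL stood at 3540 RPKM at 20% O2 against 182.5 at 5% O2, and hflK at 2404 in batch against 62.5 and 64.5 in the bioreactor. For amoA, lower at 20% than at 5% O2 in the deposited values, quantile scaling gave 0.47 on the log2 scale. That value follows its rank among the highest genes and not its level.

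Camera called 9 of 19 lists, all higher at 20% O2. All 50 ribosomal protein genes rose, with a median of 1.99 (adjusted p = 6.3e-32, and adjusted p = 0.079 with an estimated correlation), among them rpsH (2.32) and rplE (2.26). Of 31 amino acid synthesis genes 22 rose and 9 did not pass (median 0.93, adjusted p = 1.4e-08, and adjusted p = 0.2 with an estimated correlation). Examples were hisA (1.74) and hisF (1.76) of histidine synthesis, thrC (1.68), for threonine synthase, and ilvC (1.47), of branched-chain synthesis. Of 17 aminoacyl-tRNA synthetase genes 14 rose (median 0.80, adjusted p = 5e-07, and adjusted p = 0.066 with an estimated correlation), led by pheT (2.34) and pheS (2.41), which charge tRNA with phenylalanine. In the list of hopanoids and carotenoids, 10 of 13 genes rose, 1 fell and 2 did not pass (median 0.85, adjusted p = 0.00031, and adjusted p = 0.084 with an estimated correlation). No crt gene, of carotenoid synthesis, was matched to that list. The risers included ispF (1.90), ispD (2.00) and a copy of dxs (MEALZv4_1323, 1.78), which make isoprenoid precursors, whereas 1 copy of shc (MEALZv4_2523), for the hopanoid-forming cyclase, was the gene that fell. The other copy of shc (MEALZv4_3097), which was named after its values were seen, rose by 1.03 (adjusted p = 0.0044), and by 0.65 (adjusted p = 0.029) without replicate 1 at 5% O2.

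Among 20 heat shock and protease genes 10 rose and 3 fell (median 0.47, adjusted p = 0.00085, and adjusted p = 0.29 with an estimated correlation), and grpE, the nucleotide exchange factor of DnaK, rose by 1.94. For replication and cell division, 10 of 19 rose and 2 fell (median 0.42, adjusted p = 0.0056, and adjusted p = 0.097 with an estimated correlation), with ftsB (2.43) and ftsZ (1.81) of the division machinery higher and minC (-1.34), a division inhibitor, lower. In nitrogen assimilation, 5 of 11 rose and 2 fell (median 0.53, adjusted p = 0.012, and adjusted p = 0.12 with an estimated correlation), the risers including glnA, for glutamine synthetase (2.50), and ntrC, a regulator of nitrogen genes (1.15). For EMP glycolysis 6 of 9 rose and 1 fell (median 0.83, adjusted p = 0.0054, and adjusted p = 0.21 with an estimated correlation). Its members included eno, for enolase (2.22), and pyk, for pyruvate kinase (1.26), while fba (-1.73), an aldolase gene, fell. The tags of eno, ftsB, ispD and ispF run in sequence from MEALZv4_1462 to MEALZv4_1465. Their rises, spread over the lists of glycolysis, cell division, and hopanoids and carotenoids, may therefore not be independent. Of 6 ATP synthase genes, atpD (MEALZv4_0335, 2.44), atpG and atpA (2.19) were among 4 that rose, and another copy of atpD (MEALZv4_3735, -2.29) fell (median 1.80, adjusted p = 0.017, and adjusted p = 0.27 with an estimated correlation). For atpA, at 303 and 758 RPKM in the 5% O2 libraries, the rise was 1.53 without replicate 1 and 2.85 without replicate 2 at 5% O2. With quantile scaling the adjusted p was 0.19 for EMP glycolysis and 0.19 for ATP synthase, and with median-ratio scaling it was 0.073 for ATP synthase; pyk moved to 0.82 with quantile scaling. Adjusted over the list alone, 24 amino acid, 11 heat shock and 5 ATP synthase genes were higher, and the counts of the other 6 called lists were the same.

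Camera did not call the other 10 lists. In the list of pyruvate dehydrogenase and the TCA cycle, which oxidizes acetyl-CoA, 5 of 15 rose and 6 fell (adjusted p = 0.94), with acnA, fumC and sdhC (-1.84) lower and a copy of sucD (MEALZv4_3215, 1.78) higher. The hydrogenase list held 5 hyp genes, which serve hydrogenase maturation, and 4 fell (median -1.04, adjusted p = 0.053), including hypB (-1.75) and hypE (-1.04). That adjusted p was 0.049 without replicate 1 at 20% O2 and 0.037 without replicate 1 at 5% O2. Of 8 genes for formaldehyde and formate oxidation 3 rose (adjusted p = 0.065; 0.049 without replicate 1 at 20% O2 and 0.034 without replicate 2 at 5% O2). Among them, fae (MEALZv4_2428), for the formaldehyde-activating enzyme, went from 1703 to 8274 RPKM (2.30), and fhcD rose by 0.81. Among terminal oxidases and the bc1 complex, 1 of 6 rose and 2 fell, namely coxB (MEALZv4_1170, -2.18) and ctaD (MEALZv4_1171, -1.71), with a list median of 0.02, a mean of -0.44 and a camera test on the lower side (adjusted p = 0.97). With median-ratio scaling 3 were higher and 2 lower, and with quantile scaling 0 and 2. In sucrose and glycogen metabolism 4 of 11 fell (adjusted p = 0.54), including a copy of glgP (MEALZv4_2538), for glycogen phosphorylase, with adjusted p = 3.4e-06, and a copy of glgB (MEALZv4_3507, -1.10), for the branching enzyme. For phosphate and sulfate 2 of 19 rose and 7 fell (adjusted p = 0.97), with a median of -0.22 that was 0.04 with median-ratio and 0.08 with quantile scaling. The calls of that list were 6 higher and 5 lower with median-ratio scaling, and 6 higher and 4 lower with quantile scaling. In the deposited values cysT, for a sulfate permease, fell by 1.70. In oxidative stress, 1 of 6 rose and 1 fell (adjusted p = 0.54), namely sodB, for superoxide dismutase (1.42, and 0.70 with quantile scaling), and msrA (-0.86). For iron uptake and storage 2 of 5 rose and 1 fell (adjusted p = 0.21), with one bfr copy (MEALZv4_1141, -1.17) lower and another (MEALZv4_1724, 1.09) higher. In the Entner-Doudoroff and oxidative pentose phosphate routes 1 of 5 rose and 2 fell, gnd (-1.20) and zwf (MEALZv4_3918, -0.95), with a median of 0.28, a mean of -0.21 and a camera test on the higher side (adjusted p = 0.92). The calls of these routes were 3 higher and 2 lower with median-ratio scaling, and 2 and 2 with quantile scaling. For the 5 pqq genes of the methanol dehydrogenase and PQQ list, limma called 0, and 0 at unadjusted p under 0.05 (adjusted p = 0.54 for the list; 0.59 with fry).

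In lists too short to test, both nqr genes of the sodium-pumping NADH dehydrogenase rose (nqrE 1.70, nqrF 1.81), as did nirB and nirD (2.54) of nitrite reduction. Both RuMP entry genes, hxlB (0.69, adjusted p = 0.013) and hxlA (0.44, adjusted p = 0.028), passed. Without replicate 1 at 5% O2 they stood at 0.35 (adjusted p = 0.064) and 0.25 (adjusted p = 0.12), without replicate 2 at 20% O2 at adjusted p of 0.098 and 0.16, and hxlA without replicate 1 at 20% O2 at 0.063. In pentose phosphate rearrangement 2 of 4 genes rose, rpiA (MEALZv4_3436, 0.68) and tkt (0.93, and 0.60 without replicate 1 at 5% O2). The methane monooxygenase genes amoA (-0.50, adjusted p = 0.013) and amoB (-0.38, adjusted p = 0.02) were lower, and amoC stood at 0.03 (adjusted p = 0.85). With median-ratio scaling amoA and amoB were -0.21 and -0.10 (adjusted p = 0.38 and 0.64), with quantile scaling 0.47 and 0.03, and without replicate 2 at 20% O2 their adjusted p was 0.12 each. These 3 genes held 11.8% ± 0.97 of summed RPKM at 5% O2 and 10.4% ± 0.46 at 20% O2 (SD, n = 2 each). Quantile scaling sets values by rank, so for these genes, the highest in batch, it shows changes of rank and not of level. The ectoine gene ectA fell by 1.96 and the pilus gene pilW rose by 1.41. The copper list held only 2 genes, both matched by the symbol corA, and their products were not looked up. Of these, MEALZv4_2831 rose by 1.29. Of the 4 genes in the fixed CRISPR list, only cas3 (MEALZv4_1346) was called, as higher (0.89). In the fixed list of flagella and chemotaxis, which held 4 genes and none of the flg and fli genes named above, flhF was lower (-0.57, adjusted p = 0.039), and 0 were lower when adjusted over the list alone, against 1 at unadjusted p under 0.05; with median-ratio scaling flhF stood at -0.29 (adjusted p = 0.24). Its call also ended without replicate 1 (0.16) or 2 (0.094) at 20% O2 and without replicate 1 (0.14) or 2 (0.056) at 5% O2. Of the 2 genes in the fermentation list acs was lower (-0.44, adjusted p = 0.041). That call ended with median-ratio (0.45) and quantile scaling (0.48), and without batch replicate 1 (0.055), 2 (0.056) or 3 (0.061). It also ended without any 1 of the bioreactor libraries. Of the serine cycle list glyA stood at 0.30 (adjusted p = 0.33).

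**Figure D3:**
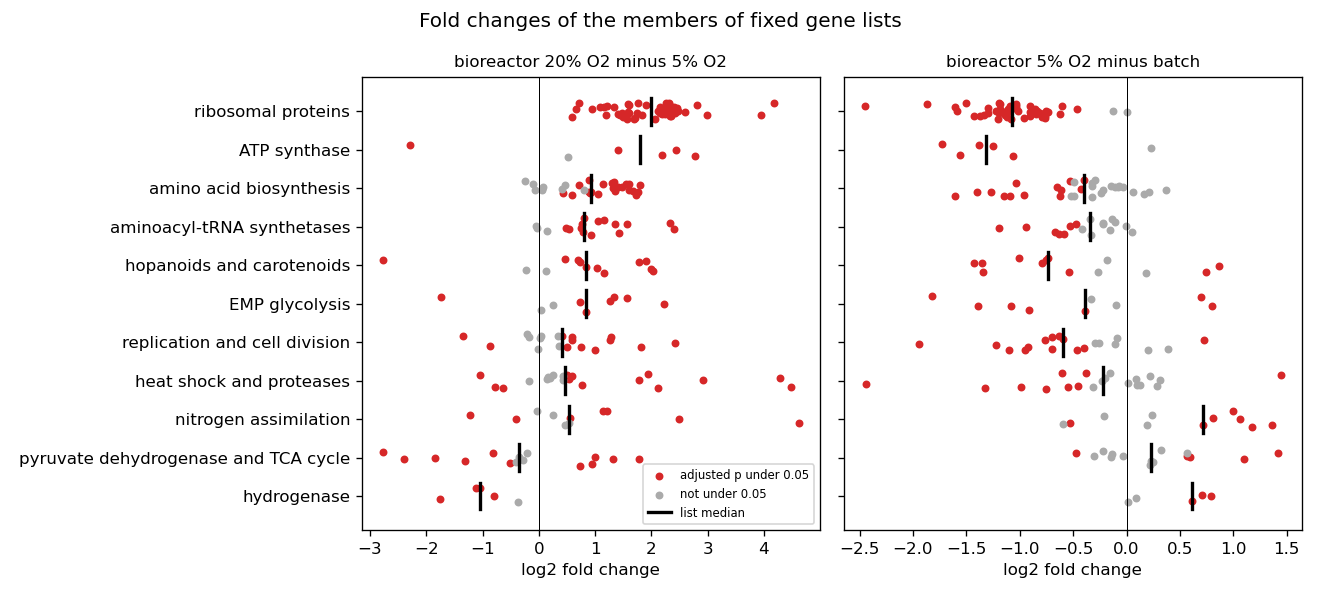
Log2 fold changes of the members of 11 gene lists (horizontal axes) for 20% minus 5% O2 in the bioreactor, left, and the 5% O2 bioreactor minus batch, right; each point is a gene, red where adjusted p was under 0.05, and black bars are list medians. Ribosomal protein genes had medians of 1.99 and -1.07.

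The 5% O2 bioreactor was compared with batch culture, which had the same stated gas mix. Feed, density and stage in the bioreactor are not given, so they cannot be told apart from culture type. The names of the batch libraries hold no date-like token, so day or run cannot be told apart from it either. The flagellar genes fliD, fliS, flgB, flgC, flgE, flgJ, flgK, flgL and flgM were higher in the bioreactor. Lower were 48 of 50 ribosomal protein genes, 5 of 6 ATP synthase genes, both ectoine genes of the list, and hflK, hflC and ftsH at the tags MEALZv4_4003 to MEALZv4_4005. The largest rise among named genes was that of fliD, from 1285 ± 203 (SD, n = 4) to 10262 ± 694 RPKM (SD, n = 2; log2 fold change 3.01, SE 0.15, adjusted p = 7e-07). The largest fall was that of hflK (MEALZv4_4003), for a membrane protein that binds the protease FtsH, from 2404 ± 1767 to 62.5 ± 2.1 RPKM (-4.87, SE 0.60, adjusted p = 0.00016).

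Of the 4001 genes, limma called 1776 (44.4%), 1051 higher and 725 lower in the bioreactor, 394 and 245 of them by at least 2-fold. The all-gene median was 0.136. With median-ratio and quantile scaling the calls split 871 to 905 and 828 to 857, so that 49% and 49.1% were higher in place of 59.2%. Besides fliD, the rises were those of fliS (2.91), flgL (2.64), flgM (2.30), flgK (2.15), flgJ (2.11), flgE (1.95), for the hook protein, flgB (1.94) and flgC (1.93), for the rod, pseG (2.12), which serves the synthesis of pseudaminic acid, a sugar found on flagellins, vgrG (2.10) and tagD (1.89). Besides that copy of hflK, the falls were those of hflC (MEALZv4_4004, -3.92) and ftsH (MEALZv4_4005, -2.44), of cysT (-2.43) and cysW (-2.25), for sulfate permeases, and of ectB (-2.27), for a transaminase of ectoine synthesis. Also lower were rplJ (-2.45), rplL (-1.87), ftsB (-1.95), fnr (-1.83), eno (-1.82) and cobM (-1.80).

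Camera called 7 of 19 lists, all lower in the 5% O2 bioreactor. Of 50 ribosomal protein genes 48 fell (median -1.07, adjusted p = 3.8e-23, and adjusted p = 0.1 with an estimated correlation), such as rpsF (-1.43) and rpsR (-1.61). In amino acid synthesis 13 of 31 fell (median -0.40, adjusted p = 0.00035, and adjusted p = 0.38 with an estimated correlation), including leuC (-1.04) and a copy of hisC (MEALZv4_2497, -0.96). For replication and cell division 12 of 19 fell and 1 rose (median -0.59, adjusted p = 8e-04, and adjusted p = 0.1 with an estimated correlation), among them dnaX (-1.10), for DNA polymerase subunits, and gyrA (-0.92), for DNA gyrase. Of 17 aminoacyl-tRNA synthetase genes 7 fell (median -0.34, adjusted p = 0.0011, and adjusted p = 0.1 with an estimated correlation), such as metG (-1.19) and ileS (-0.94). For ATP synthase 5 of 6 fell (median -1.32, adjusted p = 0.0053, and adjusted p = 0.3 with an estimated correlation), with atpD (MEALZv4_0335, -1.56) and atpB (-1.25). In the list of hopanoids and carotenoids 8 of 13 fell and 2 rose (median -0.73, adjusted p = 0.0081, and adjusted p = 0.17 with an estimated correlation), with ispF (-1.35) and ispD (-1.43) lower and ispH (0.75) higher. By tag, ispF and ispD are the neighbours of ftsB and eno, so the falls of these genes may not be independent either. For EMP glycolysis 5 of 9 fell and 2 rose (median -0.39, adjusted p = 0.04, and adjusted p = 0.38 with an estimated correlation), with pyk (-1.39), eno and gap (-1.08), for glyceraldehyde phosphate dehydrogenase, lower. Adjusted over the list alone, 12 amino acid and 8 aminoacyl-tRNA synthetase genes were lower, and the counts of the other 5 called lists were the same. The EMP glycolysis call ended with median-ratio (0.08) and quantile scaling (0.22), and without batch replicate 1 (0.05), replicate 1 (0.053) or 2 (0.052) at 20% O2, or replicate 1 at 5% O2 (0.16). Without replicate 1 at 5% O2 the adjusted p was also 0.052 for aminoacyl-tRNA synthetases and 0.096 for hopanoids and carotenoids.

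Among lists not called, 6 of 11 nitrogen assimilation genes rose and 1 fell (adjusted p = 0.21), such as ureG (1.36), for a urease accessory protein, and ald (1.18), for alanine dehydrogenase. Of 20 heat shock and protease genes 8 fell and 1 rose, clpB (1.45), for a disaggregating chaperone (adjusted p = 0.084; 0.043 without batch replicate 2 and 0.0034 without replicate 2 at 5% O2). In phosphate and sulfate 10 of 19 rose and 2 fell (adjusted p = 0.36), and in the TCA cycle list 4 of 15 rose and 1 fell (adjusted p = 0.39), with acnA (1.42) and fumC (1.10) higher. Of 5 hydrogenase genes 3 rose (adjusted p = 0.21), led by hypB (0.71) and hypE (0.79). In oxidative stress 3 of 6 rose (adjusted p = 0.48), led by msrA (0.63), and in sucrose and glycogen 2 of 11 rose, led by a copy of glgP (MEALZv4_2538, 0.72), with a list median of 0.07 that was -0.04 with median-ratio and -0.02 with quantile scaling (adjusted p = 0.95). For terminal oxidases and the bc1 complex 2 of 6 rose and 3 fell (adjusted p = 0.41). In iron uptake and storage 1 of 5 rose, feoB (MEALZv4_2279, 1.57), and 2 fell, fur (-0.98) among them. The median of that list was 0.07 (-0.04 with median-ratio scaling) and the camera test lay on the lower side (adjusted p = 0.64). In formaldehyde and formate oxidation 1 of 8 fell, fae (MEALZv4_2428, -1.18), with a median of 0.04, a mean of -0.17 and a camera test on the lower side (adjusted p = 0.39), and that median was -0.07 and -0.21 with median-ratio and quantile scaling. In the Entner-Doudoroff list zwf (MEALZv4_4018, -0.49) and among the pqq genes of the methanol dehydrogenase and PQQ list pqqA (-0.67) was the gene of 5 that was lower (adjusted p = 0.36 for both lists). Without replicate 1 at 5% O2, that copy of zwf stood at -0.27 (adjusted p = 0.18), and without replicate 2 at 5% O2, pqqA stood at -0.45 (adjusted p = 0.063). Of the short lists, all 4 CRISPR genes rose, such as cas3 (MEALZv4_1346, 1.07) and cas2 (MEALZv4_1352, 1.37), although the other cas3 (MEALZv4_3721, 0.66) did not pass with quantile scaling (0.17) or without replicate 1 at 5% O2 (0.051). In other short lists, both ectoine genes fell (ectA -1.69), all 3 pilus genes fell (pilQ -1.03), both nqr genes fell (nqrE -1.04), and both genes of the fermentation list rose (pta 0.84, acs 0.69). In the fixed list of flagella and chemotaxis, which held 4 genes and none of the fli and flg genes named above, flhF was higher (0.79) and the list median was 0.16. The pentose phosphate gene rpe was lower (-0.74). For amoC, the highest gene in batch, a value of 0 with quantile scaling shows an unchanged rank only. Of the monooxygenase genes amoC was lower (-0.30, adjusted p = 0.036), at 0 with quantile scaling and with adjusted p of 0.074 without batch replicate 2, 0.11 without batch replicate 3, 0.1 without batch replicate 4, and 0.054 without either library at 20% O2.

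Both bioreactor groups, weighted equally, were compared with batch, since the labels divide the libraries by culture type. In the mean of both bioreactor groups, 9 of 11 nitrogen assimilation genes and the CRISPR genes named below were higher. Lower were ectA and ectB of ectoine synthesis, the sulfate permease genes cysT and cysW, and hflK, hflC and ftsH at the tags MEALZv4_4003 to MEALZv4_4005. The largest rise among named genes was that of a copy of cas4 (MEALZv4_1350), of the CRISPR adaptation machinery, at 25.8 ± 7.1 RPKM in batch (SD, n = 4) and 81 ± 2.8 and 141.5 ± 19.1 in the 5% and 20% O2 bioreactor (SD, n = 2 each; log2 fold change 2.05, SE 0.18, adjusted p = 2.6e-05). The largest falls were those of hflK (MEALZv4_4003, -4.84, SE 0.49, adjusted p = 4.9e-05) and hflC (MEALZv4_4004, -3.85).

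Limma called 1683 genes (42.1%), 804 higher and 879 lower, around an all-gene median of -0.008. A fit with only 2 groups, batch and bioreactor, in which the difference between gas mixes enters the spread, called 507 genes, 231 higher and 276 lower. Further rises were those of urtD (MEALZv4_1766, 1.98), of a urea transporter, cas5c (MEALZv4_1347, 1.92), cas6 (1.76), cas1c (MEALZv4_1351, 1.72), cas8c (MEALZv4_1348, 1.65) and 2 copies of cas7c (MEALZv4_1349, 1.62, and MEALZv4_2159, 1.61), of CRISPR defence, sufC (1.86), sufB (1.76) and sufD (1.68), of iron-sulfur cluster assembly, and nirD (1.67). Further falls were those of cysT (-3.28), cysW (-2.94), ectA (-2.67), ectB (-2.49), thpD (-1.69), for ectoine hydroxylation, fnr (-2.53), ftsH (MEALZv4_4005, -2.36), msrP (-1.56), for repair of oxidized methionine, dnaX (-1.54) and minC (-1.26). In the 2-group fit sufB (adjusted p = 0.11), sufC (0.087), sufD (0.12) and nirD (0.12) did not pass. For these 4 genes the 20% O2 group lay farther from batch than the 5% O2 group. Mean RPKM in batch, at 5% and at 20% O2 (SD, n = 4, 2 and 2) was 40 ± 6.5, 54 ± 5.7 and 343 ± 2.8 for sufB, 57.2 ± 5.6, 88.5 ± 24.7 and 507.5 ± 2.1 for sufC, 51 ± 4.5, 67 ± 1.4 and 403 ± 21.2 for sufD, and 164.5 ± 24.2, 216 ± 2.8 and 1263.5 ± 43.1 for nirD.

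The nitrogen assimilation list was the only one of 19 called, with 9 of 11 genes higher and 1 lower (median 1.13, adjusted p = 0.0019, and adjusted p = 0.19 with an estimated correlation), and the same counts adjusted over the list alone. Against batch, camera called this list at 20% O2 (8 of 11 higher and 1 lower, adjusted p = 0.00036). It was not called at 5% O2 (6 of 11 higher and 1 lower, adjusted p = 0.21). Its leading members were ureG (1.60) and ureE (1.33), for urease accessory proteins, and ntrC (1.29) and glnL (1.42), for a pair of nitrogen regulators. Without replicate 2 at 5% O2, ATP synthase was called as well (adjusted p = 0.0037). Ribosomal protein genes, with 2 of 50 higher and 7 lower, had a median of -0.01 (0.02 with median-ratio scaling, adjusted p = 0.63). Heat shock and protease genes, with 7 of 20 higher and 3 lower, had a median of -0.10 (0.02 with quantile scaling), a mean of 0.18 and a camera test on the higher side (adjusted p = 0.63), and amino acid genes, with 3 of 31 higher and 3 lower, had a median of 0.04 and a mean of -0.01 (adjusted p = 0.82). Against batch, ribosomal protein medians were -1.07 at 5% O2 and 1.02 at 20% O2, and amino acid medians -0.40 and 0.39. The equal-weight medians of these 2 lists therefore average opposite shifts. In phosphate and sulfate, the list that holds cysT and cysW, 8 of 19 genes were higher and those 2 lower (median 0.30, adjusted p = 0.24). The monooxygenase genes amoA (-0.40), amoB (-0.29) and amoC (-0.28) were lower, but their adjusted p with median-ratio scaling was 0.052, 0.11 and 0.11. With quantile scaling, which for the highest genes follows rank and not level, these genes stood at -0.30, 0.05 and 0. Their calls also ended in the 2-group fit (0.49, 0.62 and 0.65), and those of amoB and amoC without batch replicate 3 (0.07 and 0.081) or 4 (0.058 and 0.075) or replicate 2 at 20% O2 (0.074 and 0.057), of amoB without batch replicate 2 (0.062) and of amoC without replicate 1 at 20% O2 (0.051).

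The 20% O2 bioreactor differed from batch in both culture type and gas. Higher were glnK, a nitrogen signalling gene, nirB of nitrite reduction, groES of the chaperonin, and sufB and sufC of iron-sulfur cluster assembly. Lower were hflK and hflC at the tags MEALZv4_4003 and MEALZv4_4004, the sulfate permease genes cysT and cysW, and ectA of ectoine synthesis. The largest rise among named genes was that of glnK, from 131.2 ± 80.9 (SD, n = 4) to 1843 ± 98.3 RPKM (SD, n = 2; log2 fold change 4.03, SE 0.51, adjusted p = 0.00011). Limma called 2088 genes (52.2%), 769 higher and 1319 lower, around an all-gene median of -0.164. The split was 1047 to 1015 with median-ratio and 979 to 1024 with quantile scaling, 50.8% and 48.9% higher in place of 36.8%. After glnK, the rises were led by nirB (3.74), groES (3.51), sufC (3.13), sufB (3.08) and feoB (MEALZv4_2489, 2.97), and included urtD (MEALZv4_1766, 2.77) and cas5c (MEALZv4_1347, 2.64). The falls were led by hflK (MEALZv4_4003, -4.82), cysT (-4.13), hflC (MEALZv4_4004, -3.78), ectA (-3.65), cysW (-3.64) and fnr (-3.23), and included smbP (-2.21) and 2 copies of istB, of insertion sequences (MEALZv4_2264, -2.32, and MEALZv4_1302, -2.24), a symbol with several copies among which reads were not told apart by any source used here.

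List tests of the 20% O2 bioreactor against batch were not planned and were chosen after other results were seen. Camera called 4 of 19 lists, all higher in the bioreactor. Of 50 ribosomal protein genes 40 rose (median 1.02, adjusted p = 5.7e-16, and adjusted p = 0.2 with an estimated correlation), and with quantile scaling 31 were higher and 3 lower. In nitrogen assimilation 8 of 11 rose and 1 fell (median 1.60, adjusted p = 0.00036, and adjusted p = 0.16 with an estimated correlation). Of 31 amino acid synthesis genes 14 rose (median 0.39, adjusted p = 0.00036, and adjusted p = 0.43 with an estimated correlation), and of 17 aminoacyl-tRNA synthetase genes 10 rose and 1 fell (median 0.42, adjusted p = 0.0055, and adjusted p = 0.2 with an estimated correlation). Adjusted over the list alone, 44 ribosomal protein and 13 amino acid genes were higher, and the counts of the other 2 called lists were the same. Heat shock and protease genes, with 9 of 20 higher and 5 lower, were not called (adjusted p = 0.052). They were called with quantile scaling (0.039), without batch replicate 1 (0.037), 3 (0.038) or 4 (0.049) and without replicate 2 at 20% O2 (0.024). In phosphate and sulfate 5 of 19 were higher and 2, cysT and cysW, lower (adjusted p = 0.24).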

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

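All tests in this part were planned before their results were seen except the count expected from unchanged groups, the count expected of independent lists and the divided batch libraries.

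In batch growth, 7 of 211 values stood apart from the other 3 libraries by Dixon's criterion, over 181 genes and the list medians, and chance sets about 1 in 20 apart. Batch replicate 4 held 4 of them: atpG at 615 RPKM (825 to 868 in the others), rpsF at 2481 (2004 to 2077), tpiA at 3693 (2588 to 2611) and hisC (MEALZv4_2497) at 179 (217 to 223). For moxG it was batch replicate 1, at 12991 RPKM (10942 to 11085 in the others). In batch replicate 3, cas3 (MEALZv4_3721) was at 22 RPKM against 26 in each of the others, and the median of the RuMP entry genes at 6042.5 against 6357 to 6381.

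Genes that changed from batch in opposite directions at the gas mixes numbered 429, of which 138 were lower at 5% O2 and higher at 20% O2 and 291 the reverse, while another 584 passed in the same direction. The limma test of 20% against 5% O2 called each of them too, which adds no support, since opposite calls against the same batch libraries all but fix that outcome. Independent lists of these sizes would give 486 opposite genes, simulated unchanged groups gave 0 in each of 20 simulations with limma, and dividing the batch libraries between the comparisons in 6 ways gave 249 to 536 in a 4-group fit and 195 to 435 in separate fits, so the number is not above that of independent lists. Library scaling is argued against as the whole cause, since the lower of the counts with median-ratio and quantile scaling was 385, and so is the spread of the 5% O2 libraries, since the count was 364 without replicate 1 and 509 without replicate 2. A response to the gas mix and a difference in bioreactor day or run stay open and untested, and a difference in vessel stays open, since the meaning of the name tokens is not given.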

How the results depend on the processing

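The list tests of the 20% O2 bioreactor against batch and the counts at unadjusted p were chosen only after results were seen. The counts of changed genes kept within 1.5 times under all alternatives except in the equal-weight comparison of bioreactor with batch, where 1683 became 507 in the 2-group fit, whose spread takes in the difference between gas mixes, and 1092 with the replicate number as a block. The block used libraries 1 and 2 only, and its counts elsewhere were 2153 for 20% against 5% O2, 1313 and 1696 for the 5% and 20% O2 bioreactor against batch, with 9, 7, 1 and 5 lists called for 20% against 5% O2, the 5% O2 bioreactor, the equal-weight comparison and the 20% O2 bioreactor. Same-numbered libraries deviated with correlations of -0.044 to 0.092, so the numbers do not pair them. In that order, camera called 9, 7, 1 and 4 lists as reported. With an estimated correlation it called 0, 0, 0 and 0, against 5, 4, 1 and 3 at unadjusted p under 0.05, and fry, which does not compare a list with other genes, called 16, 11, 7 and 14. Leaving out ribosomal proteins or using median-ratio scaling gave 8, 6, 1 and 4 lists, and quantile scaling 7, 6, 1 and 5.

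Leaving out 1 library at a time gave 1681 to 2351 genes for 20% against 5% O2, 1431 to 1766 for the 5% O2 bioreactor, 1438 to 2277 for the 20% O2 bioreactor and 1295 to 1792 for the equal-weight comparison, and 9 to 11, 4 to 8, 1 to 2 and 4 to 5 lists in the order of the list counts above; a group left with 1 library is assumed to vary like the others. The log2 ratio of EMP to Entner-Doudoroff genes was 1.597 to 1.697, and 1.332 with means of log2 values, a change whose cause was not tested. The ratio of the RuMP entry median to glyA was 4.522 to 4.75. Of 4648 alternatives of 332 called results on named genes, 4393 kept direction and call, 251 kept direction only and 4 reversed, and 12 of 182 alternatives of 13 results that had not passed changed sign, with the most losses in the 2-group fit (61) and the block (34).

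Signs reversed as follows. Quantile scaling sets values by rank, so for the highest genes, such as the amo genes, it shows changes of rank and not of level. For amoC, the highest gene in batch, a value of 0 shows an unchanged rank only. Other causes were not tested. With quantile scaling, amoA, amoB and amoC stood at 0.47, 0.03 and 0 for 20% against 5% O2; amoB, hxlA, hxlB and MEALZv4_0585 at 0.03, -0.33, -0.34 and -0.25 for the 5% O2 bioreactor; and amoB, hxlB and hxlA at 0.05, -0.04 and -0.12 for the equal-weight comparison. With median-ratio scaling, hxlA, hxlB and MEALZv4_0585 stood at -0.09, -0.04 and -0.01 for the 5% O2 bioreactor. Over the left-out libraries of that comparison, MEALZv4_3279 ranged from -0.86 to 0.08, hxlA from -0.17 to 0.22 and hxlB from -0.26 to 0.41. For the equal-weight comparison, fitting only the compared groups is the fit already reported. Lists were matched by symbol or synonym throughout, so matching by symbol only was the main result itself and tested nothing. The patterns of product names that were fixed with the lists were not applied. The mxaF to xoxF and pfp to edd ratios were not run, as those genes were not named. Read depth is unknown, and rounding to whole RPKM limits genes near the minimum of 5.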

Other observations

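The gene families by shared symbol stem, the unnamed genes with their values without a library, and the values per library were chosen after their values were seen, as were the tests of library scaling and of day or run for ribosomal proteins and the test of copies of each ist symbol.

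Grouped by symbol stem, 55 families were tested with camera, and 21 were called for 20% against 5% O2 and 17 for the 5% O2 bioreactor against batch. Against batch, 11 were called for the 20% O2 bioreactor and 7 for the bioreactor mean. No family was called with an estimated correlation, where the lowest adjusted p of camera was 0.17. All 10 flg genes, which include those of the flagellar hook and rod, were lower at 20% than at 5% O2 (median -2.16, adjusted p = 8.7e-05, and adjusted p = 0.31 with an estimated correlation) and higher in the 5% O2 bioreactor than in batch (median 1.95, adjusted p = 7.6e-07, and adjusted p = 0.39 with an estimated correlation). Of 15 fli genes, also flagellar, 13 were lower at 20% O2 (median -0.77, adjusted p = 0.0076, and adjusted p = 0.5 with an estimated correlation), 7 with median-ratio scaling and 9 with quantile scaling. In the 5% O2 bioreactor 9 of them were higher than in batch (median 0.82, adjusted p = 0.0058, and adjusted p = 0.5 with an estimated correlation). All 5 suf genes, of iron-sulfur cluster assembly, were higher at 20% O2 (median 2.53, adjusted p = 5e-05, and adjusted p = 0.2 with an estimated correlation), as were all 7 sec genes, of protein export (median 1.12, adjusted p = 8.7e-05, and adjusted p = 0.2 with an estimated correlation), and 10 of 11 his genes (median 1.33, adjusted p = 3.3e-05, and adjusted p = 0.2 with an estimated correlation). Of 22 cas genes, of CRISPR defence, 21 were higher in the bioreactor mean than in batch (median 1.18, adjusted p = 7e-12, and adjusted p = 0.21 with an estimated correlation). At 20% against 5% O2, 11 of the 22 were higher and 0 lower (median 0.49, adjusted p = 0.00016, and adjusted p = 0.2 with an estimated correlation). Of 10 tss genes, of type VI secretion, 8 were lower in the bioreactor mean than in batch (median -0.71, adjusted p = 0.00046, and adjusted p = 0.73 with an estimated correlation). The direction of these families was the same under both scalings.

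The unnamed gene MEALZv4_2286 was at 10 ± 2.8 RPKM at 5% O2 and 556 ± 1.4 at 20% O2 (log2 fold change 5.69), and MEALZv4_2285 at 25.5 ± 10.6 and 1029 ± 43.8 (5.34; SD, n = 2 each). The other way, MEALZv4_2820 was at 4394 ± 2799 and 35 ± 0 (-6.77), and MEALZv4_2316 at 4857 ± 2828 and 41.5 ± 10.6 (-6.73). The 5% O2 libraries were at 6373 and 2414 RPKM for MEALZv4_2820 and at 2857 and 6857 for MEALZv4_2316. Without replicate 1 or 2 at 5% O2, the log2 changes were -6.07 or -7.47 and -7.36 or -6.09. Values of several genes differed between the 4 batch libraries, which lay at 15.38, 21.8, 23.15 and 14.92 on the second principal component in the order of replicates 1 to 4. In that order, glnK was at 181, 59, 66 and 219 RPKM, groL at 664, 345, 316 and 587, and ftsZ at 711, 368, 349 and 626. In batch replicates 1 to 4, hflK (MEALZv4_4003) was at 972, 3840, 4023 and 782 RPKM, hflC (MEALZv4_4004) at 776, 2699, 3108 and 618, and ftsH (MEALZv4_4005) at 1338, 3152, 3289 and 1132. In the bioreactor libraries these copies of hflK, hflC and ftsH were at 61 to 65, 87 to 106 and 322 to 415. In the same order of batch replicates, another copy of hflK (MEALZv4_3061) was at 1548, 2153, 2239 and 1416 RPKM, another of hflC (MEALZv4_3060) at 1266, 1362, 1541 and 1073, and other copies of ftsH at 414, 376, 372 and 434 (MEALZv4_1809) and at 196, 215, 215 and 198 (MEALZv4_3622).

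Ribosomal protein genes were higher at 20% than at 5% O2, with a list median of 1.99. Library scaling and expression level are argued against as the whole cause, since 45 of the 50 genes were called higher with quantile scaling, where the list median was 1.54, and the list median as deposited lay at percentile 100 of 10000 random lists matched on mean expression, whose highest median was 1.08. A day or run of the bioreactor libraries cannot be told apart from the gas mix, since 0 date-like name tokens occurred in both gas groups. The gas mix itself, and a growth rate that may have differed with it, stay open and untested.

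All 10 istA and istB genes, of insertion sequences, were lower at 20% than at 5% O2, and 10 of 10 stayed lower with median-ratio scaling, which argues against scaling. Reads shared between near-identical copies are one candidate explanation for the uniform change. The test planned first, over both symbols together, left it undecided, since the SD of the log2 changes (0.44) lay at percentile 37.9 of matched sets of genes that fell. Within each symbol, which has 5 copies, the SD was 0.16 against a median of 0.5 in matched sets, at percentile 0.51, as shared reads would give. Regulation common to all copies was not tested and would give the same, so the 10 genes may not be 10 independent measurements.

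Other divisions of the 8 libraries into 4 and 4 were run for culture type in the 2-group fit. The real division called 507 genes with limma, the highest of the other 34 called 0 (945 at unadjusted p under 0.05, against 1104 for the real one), and 1 of 35 divisions, the real one, gave as many, the smallest share that 35 divisions allow. Every other division puts batch libraries on both sides, so libraries alike within groups give this outcome whatever the cause. It cannot be tied to culture type. Chance can be excluded for that count only as far as the 8 libraries are exchangeable, which the pairs at each gas mix limit, as would a vessel shared by the 5% O2 libraries. The batch libraries also paired, with Pearson correlations of 0.9895 (replicates 2 and 3) and 0.986 (1 and 4) against 0.9684 to 0.978 otherwise. For gene lists, 33 of 35 divisions called at least as many as the real one, which called 1, with 10 at most, so chance cannot be excluded for that count. The divisions that called most lists, 10 each, set both 20% O2 libraries against both 5% O2 libraries, as the gas groups do.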
